A study of Caenorhabditis elegans with 44 samples.

How the data were processed

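The series holds bulk RNA-seq of whole C. elegans. Per the labels' protocols, synchronized animals grew for 51 h to young adults, about 120 worms per condition were moved to auxin or ethanol plates for 8, 16 or 24 h, RNA was extracted with Trizol, poly(A)-enriched and made into directional libraries. The titles mark every sample NHS, read here as no heat shock. The HSF-1-AID strain (JTL621) carries hsf-1 tagged with an auxin-inducible degron and GFP and expresses TIR1 from the germline promoter of sun-1, and the TIR1-only strain (CA1199) expresses TIR1 alone. The 44 libraries fall into 12 groups of strain, treatment and time, with 4 replicates per group at 8 h and 16 h and 3 at 24 h. The labels do not say whether replicates were separate cultures, so p-values measure the spread between libraries.

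Per the submitters' processing notes, the authors used STAR, featureCounts and edgeR with builds WBcel235 and ce11; versions, annotation, counting strand and the assignment of reads shared by similar genes are not stated. For each time there is a deposited table of normalized values per library and a deposited table of fold changes. The authors' normalized values are log2 CPM (reads scaled to library size) with a prior count of 2 reads, as read from the values themselves. Once that offset is removed on the linear scale, 100% of values are whole reads within a tolerance of 0.05 of a read. The deposited fold-change tables hold log2 fold changes, mean log2 CPM, the score of the authors' edgeR likelihood ratio test, a p-value and an FDR per gene. They were used only for comparison, since their header does not state the contrast. The plan had assumed linear values and a pseudocount of 0.5, with log2 values used as deposited if found, so no pseudocount was added. Each time has its own table and normalization, so all tests were made within a time.

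Of the 11430 gene identifiers listed over the tables, 11425 are in the Ensembl 115 annotation of WBcel235, which gave symbols, positions and gene types. Recovered depth was 12.5 to 50.7 M reads per library at 8 h, where the 4 libraries numbered 4 had 44.7 to 50.7 M and the others at most 26.9 M. It was 31 to 57.7 M at 16 h and 13.3 to 24.4 M at 24 h. Reads of annotated rRNA genes made up 1.26% to 31.4% of a library at 8 h (31.4% in TIR1-only ethanol replicate 3), 1.16% to 3.43% at 16 h and 3.78% to 18.3% at 24 h (18.3% in HSF-1-AID ethanol replicate 3). For genes with many reads, intervals for counting error are narrow at these depths, so the spread between libraries sets the precision. They are wide for genes with few or no reads in a group, such as clec-206, flp-1, K12D9.1 and cTel55X.1. There the prior count also bears on the fold change. No 2 replicates were copies of each other: over 60 pairs the chi-square per gene against counting noise was 5.01 to 1320.

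Genes were tested if they had at least 1 CPM in at least as many libraries as the smallest group (4 at 8 h and 16 h, 3 at 24 h). The deposited log2 values were fitted with limma 3.58.1 in R 4.3.3 (trend on, robust off), with all 4 groups of a time in 1 model and 12, 12 and 8 residual degrees of freedom. The 4 comparisons per time were HSF-1-AID auxin against ethanol (depletion), TIR1-only auxin against ethanol, the difference between these auxin effects, and HSF-1-AID against TIR1-only on ethanol. Tests were two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05 for the adjusted p. The comparisons, the gene lists, the rule for naming genes and the alternatives not listed below as later additions were chosen before the data were examined.

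The 28 gene lists, written from general knowledge of C. elegans genes, were tested with limma's camera (preset correlation of 0.01, Benjamini-Hochberg over lists), and again with a correlation estimated per list. Lists with fewer than 4 tested members were not tested, which left 27 at 16 h and 24 h, without the major sperm proteins. The lists cover cytosolic, CCT, small heat shock, ER and mitochondrial chaperones, the proteasome, meiosis, replication, germline stem cells, P granules, oocytes, sperm, vitellogenins, oxidative phosphorylation, ribosomal proteins, nucleolus, tRNA synthetases, xenobiotic metabolism, lysozymes and lectins, histones, cell death, muscle, collagens, intestine, neurons, somatic gonad and embryonic genes. Overlap of depletion calls between times was tested with a one-sided hypergeometric test over genes tested at both times.

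Genes were named by rule. For depletion these were hsf-1, the 8 largest rises and 8 largest falls in log2 with an adjusted p under 0.05, a mean above the median of tested genes, no overlap between both groups' values and no call in the same direction in the TIR1-only strain, and the 3 members with the smallest adjusted p of each called list and of the cytosolic chaperones. For the other comparisons they were the 5 largest each way under the first 3 conditions and 2 members of each called list. Fewer are printed, always the first by rule, and a gene named in any comparison may be given in others. Exceptions are marked as named after their values were seen. Values of genes with near-identical copies (major sperm proteins, histones, cyp-35A, pals, and clec-209, hsp-16.1 and hsp-16.48, each listed under 2 identifiers) are uncertain in how reads were divided. Of the named genes, hsp-90, F21C10.9, gst-5, ugt-22, rpn-7, rnr-2, egg-1 and K09H9.7 overlap exons of a gene on the opposite strand, and whether counting was by strand is not stated.

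Replicate numbers recur in every group, so pairing was checked with residuals: at 24 h all 18 same-number pairs between groups had a correlation above 0.1 (0.182 to 0.535, median 0.325 against -0.24 for different numbers). At 8 h 14 of 24 and at 16 h 15 of 24 did (medians 0.35 and 0.2, against -0.093 and -0.099 for different numbers). At 8 h HSF-1-AID auxin replicate 1 went with replicate 2 of the other groups (r = 0.606, 0.654 and 0.385). HSF-1-AID auxin replicate 2 did not (r = -0.35, -0.413 and -0.268). Only at 24 h, where all pairs passed, were the numbers treated as pairing libraries. There fits with the replicate block are printed beside results that change. The main fits at 8 h and 16 h leave out the partial structure by number. This structure was shared by all groups for replicate 4, whose same-number pairs had r from 0.455 to 0.729 at 8 h. At 16 h they had r of at least 0.481.

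The method was tested on simulated data with 50 genes changed per fold at each time. At 1.5-fold it recovered 44% at 8 h, 84% at 16 h and 52% at 24 h, at 2-fold 68%, 94% and 70%, and at 4-fold 100%. False calls were 6.61%, 4.68% and 4.84% of calls, and 0 genes were called in an unchanged comparison. The simulation changed far fewer genes than were called at 16 h and 24 h. It also drew the spread of each gene and library independently, so these shares may not carry over to the data.

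Alternatives were pseudocounts of 0.1 and 2, no filter, median-of-ratios size factors, the replicate block, an added minimum of 1.5-fold, each library left out in turn, only the 2 groups compared, an overlap threshold of 0.01 and, for lists, an estimated correlation. Added after seeing the data were a pseudocount of 0.5, limma voom on the recovered reads, library quality weights, a contrast with the mean of the other 3 groups, lists with identifiers of identical values counted once, and leaving out the deeper libraries or the library with the highest rRNA share. Permutation tests used 100000 permutations. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3. All 44 value columns were used.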

Results

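RNA was sequenced from whole young adult C. elegans kept on auxin or ethanol plates for 8, 16 or 24 h. In the HSF-1-AID strain (JTL621), the heat shock transcription factor HSF-1 carries an auxin-inducible degron. The ubiquitin ligase adapter TIR1 is made in the germline, where it marks the tagged protein for degradation once auxin is present. The TIR1-only strain (CA1199) makes the same adapter without a tagged HSF-1 and gives the background of auxin itself. Levels are library-normalized read counts (CPM), given as mean ± SD over libraries, and genes are placed on build WBcel235. Counts within gene lists fixed before the data were examined are over all genes tested and, where it differed, also adjusted over the list alone. Library depth was 12.5 to 50.7 M reads at 8 h, 31 to 57.7 M at 16 h and 13.3 to 24.4 M at 24 h.

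The hsf-1 transcript (WBGene00002004, chromosome I, 11953507 to 11963085) did not fall in the HSF-1-AID strain on auxin. At 8 h it was at 45.8 ± 7.62 CPM on ethanol and 46.9 ± 5.3 CPM on auxin (SD, n = 4; log2 fold change 0.04 ± 0.125 SE, adjusted p = 0.999). At 16 h it rose from 51.2 ± 3.34 to 70.8 ± 1.16 CPM (SD, n = 4; log2 fold change 0.47, adjusted p = 1.24e-06). At 24 h it rose from 53.8 ± 6.15 to 77.3 ± 3.43 CPM (SD, n = 3; log2 fold change 0.53, adjusted p = 5.67e-04). In the TIR1-only strain hsf-1 was at 48.8 ± 4.99 and 56.3 ± 4.8 CPM at 8 h, 67.9 ± 2.45 and 65.9 ± 3.33 CPM at 16 h and 69.6 ± 5.02 and 68.8 ± 1.16 CPM at 24 h, on ethanol and auxin. The auxin effect on hsf-1 differed between strains at 16 h (difference 0.51 in log2, adjusted p = 4.75e-05) and at 24 h (0.54, adjusted p = 0.00908). Auxin acts on the protein, so the transcript does not show whether HSF-1 was degraded.

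After 8 h on auxin, HSF-1-AID animals had less mRNA of the major cytosolic chaperones. The transcript of hsp-90, the cytosolic Hsp90 chaperone (WBGene00000915, chromosome V, 14684918 to 14688545), fell from 4362 ± 236 to 1855 ± 173 CPM (SD, n = 4; log2 fold change -1.24 ± 0.121 SE, adjusted p = 1.34e-04). The TIR1-only strain had 4661 ± 283 CPM on ethanol and 4949 ± 276 CPM on auxin. The Hsc70 chaperone hsp-1 (chromosome IV, 17278959 to 17281330) fell from 4335 to 2431 CPM (log2 fold change -0.82, adjusted p = 0.0427). Its Hsp40 partner dnj-13 (chromosome II, 11545701 to 11547360) fell from 203 ± 11.7 to 143 ± 10.6 CPM (log2 fold change -0.51, adjusted p = 0.0395). The hsp-90 call held without any 1 of the 8 HSF-1-AID libraries (adjusted p from 2.64e-04 to 0.00185). The call of hsp-1 was lost without any HSF-1-AID library except ethanol replicate 3 (adjusted p from 0.0418 to 0.21, log2 fold change from -0.91 to -0.72). That of dnj-13 was lost without any except auxin replicate 1 (adjusted p from 0.0474 to 0.192, log2 fold change from -0.55 to -0.47). Of 25 tested cytosolic chaperones and co-chaperones 3 fell, 8 when adjusted over the list alone, with a median log2 fold change of -0.25. The list moved down as a set (camera adjusted p = 1.26e-11; adjusted p = 0.0188 with an estimated correlation). The 8 subunits of the CCT chaperonin, which folds actin and tubulin, had a median of -0.24, and 3 had an unadjusted p under 0.05 in limma's test. In this list 0 were called and 2 fell when adjusted over the list alone (camera adjusted p = 2.99e-06; adjusted p = 0.473 with an estimated correlation).

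Of the 27 genes that rose at 8 h, 18 were also called higher with auxin in the TIR1-only strain, among them detoxification genes. The cytochrome P450 gene cyp-35C1 rose from 25.4 ± 12 to 113 ± 10.5 CPM in the HSF-1-AID strain (SD, n = 4; log2 fold change 2.27, adjusted p = 0.0101). In the TIR1-only strain it rose from 21.6 ± 11.1 to 108.8 ± 29.4 CPM (2.46, adjusted p = 0.00695). The glutathione S-transferase gene gst-5 (log2 fold change 1.79, adjusted p = 0.0019) and the glucuronosyltransferase gene ugt-22 (1.54, adjusted p = 0.00396) rose in HSF-1-AID animals, and in TIR1-only animals by 1.36 and 1.59. The C-type lectin gene clec-206 rose from 0.0806 to 2.34 CPM (adjusted p = 0.0019). F21C10.9, a protein-coding gene that overlaps another gene on the opposite strand, rose from 15 ± 4.83 to 40.3 ± 9.66 CPM (log2 fold change 1.44, adjusted p = 0.0425). In the TIR1-only strain F21C10.9 was at 18.5 ± 6.58 and 40.3 ± 14.9 CPM (1.13, adjusted p = 0.313). Its call was lost without any HSF-1-AID library except ethanol replicate 2 and auxin replicate 4 (adjusted p from 0.0243 to 0.214). For cyp-35C1 the adjusted p was 0.0535 without HSF-1-AID auxin replicate 3. Of the tested xenobiotic genes (cyp, ugt, gst), 11 rose, 21 when adjusted over the list alone, with a median of 0.22 (camera adjusted p = 1.91e-15; adjusted p = 0.359 with an estimated correlation).

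In all, 31 of 10971 tested genes passed at 8 h in the HSF-1-AID strain, 27 higher and 4 lower on auxin. The count was 16 without ethanol replicate 1, 20 without ethanol replicate 3, 12 without ethanol replicate 4, 11 without auxin replicate 2 and 9 without auxin replicate 3. It was 3 when the 4 deeper libraries numbered 4 were left out and 285 with library quality weights. Camera also called lower transcripts of the proteasome (median -0.08, adjusted p = 6.43e-04), meiotic pairing and recombination genes (-0.05, adjusted p = 0.0409) and replication and mitotic genes (-0.12, adjusted p = 4.08e-07). Also called lower were oocyte and eggshell genes (-0.08, adjusted p = 0.00408), ribosomal proteins (-0.13, adjusted p = 1.82e-05) and histones (-0.24, adjusted p = 6.43e-04). Camera called higher transcripts of the major sperm proteins (0.47, 28 of 28 positive, adjusted p = 9.44e-04) and lysozymes and lectins (0.09, adjusted p = 0.0413). Higher too were muscle markers (0.32, adjusted p = 0.00648) and neuron markers (0.29, adjusted p = 4.5e-04). None of these 10 calls held with an estimated correlation (adjusted p from 0.64 for replication genes to 0.738). The remaining 15 lists were not called, with camera adjusted p from 0.0682 for other sperm genes to 0.839 for vitellogenins.

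After 16 h on auxin, 32 of 32 proteasome genes rose in HSF-1-AID animals, and 13 of 26 oocyte and 22 of 38 replication genes fell. As lists these were called by camera, but not with an estimated correlation (adjusted p = 0.464, 0.713 and 0.607 with an estimated correlation). The hsp-90, hsp-1 and dnj-13 transcripts were again lower. The lid subunit gene rpn-8 rose from 234 ± 7.97 to 362 ± 15.1 CPM (SD, n = 4; log2 fold change 0.63, adjusted p = 5.1e-09), against 245 ± 2.44 and 243 ± 2.84 CPM in the TIR1-only strain. The 32 proteasome genes had a median of 0.47. The ribonucleotide reductase gene rnr-2, which supplies deoxynucleotides for replication, fell from 733 ± 33 to 525 ± 21.1 CPM (log2 fold change -0.48, adjusted p = 4.62e-07). The egg surface protein gene egg-2, needed at fertilization, fell from 370 ± 11.4 to 245 ± 24.9 CPM (-0.60, adjusted p = 6.47e-07). The hsp-90 transcript fell from 5215 ± 495 to 2371 ± 56.6 CPM (-1.13, adjusted p = 6.62e-08). In log2 hsp-1 fell by 0.73 (adjusted p = 1.89e-04), dnj-13 by 0.55 (adjusted p = 1.48e-06) and the co-chaperone sti-1 by 0.53 (adjusted p = 7.22e-06).

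Among genes above the median level that were not called in the same direction in the TIR1-only strain, the largest rise at 16 h was that of the helicase gene mel-46 (log2 fold change 1.18, from 62.8 ± 2.02 to 142 ± 12.4 CPM, SD, n = 4, adjusted p = 4.47e-09). It was followed by C16A11.3 (1.07), the sex determination factor tra-1 (0.99), the noncoding RNA linc-7 (0.97) and the ubiquitin ligase gene eel-1 (0.93). The largest fall among them was that of the annotated pseudogene WBGene00009651 (chromosome V, 14635582 to 14637751; -1.52, from 44.1 ± 2.36 to 15.6 ± 3.08 CPM, adjusted p = 2.72e-08). Next came Y4C6A.3 (-1.31), F40G12.11 (-1.25), the transporter gene snf-1 (-1.17) and the cysteine synthase-like gene cysl-3 (-1.16). In total 4288 of 10173 tested genes passed (42.2%), 2273 higher and 2015 lower. Of these, 725 calls were beyond 1.5-fold, 233 higher and 492 lower.

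At 16 h camera called 8 of 27 lists, and 0 of these calls held with an estimated correlation. Higher transcripts were found for the proteasome (camera adjusted p = 7.75e-23; adjusted p = 0.464 with an estimated correlation) and ER chaperones (12 of 19 rose, median 0.20, adjusted p = 0.00112; adjusted p = 0.535 with an estimated correlation). Higher too were aminoacyl-tRNA synthetases (13 of 20 rose, 0.17, adjusted p = 2e-04; adjusted p = 0.535 with an estimated correlation) and oxidative phosphorylation (13 of 35 rose, 8 when adjusted over the list alone, 0.13, adjusted p = 0.00177; adjusted p = 0.713 with an estimated correlation). Among these, the ER chaperone gene enpl-1 rose by 0.57, the leucyl-tRNA synthetase gene lars-1 by 0.57 and the respiratory complex gene nuo-1 by 0.32. Lower transcripts were found for replication and mitotic genes (22 of 38 fell and 3 rose, 24 and 3 when adjusted over the list alone, median -0.18, adjusted p = 1.36e-04; adjusted p = 0.607 with an estimated correlation). The same was found for oocyte and eggshell genes (13 of 26 fell and 1 rose, 17 and 1 when adjusted over the list alone, -0.19, adjusted p = 0.00164; adjusted p = 0.713 with an estimated correlation). The other two were lysozymes and lectins (18 of 65 fell and 3 rose, 16 and 3 when adjusted over the list alone, -0.21, adjusted p = 0.00921; adjusted p = 0.567 with an estimated correlation), and intestine markers (7 of 13 fell, -0.26, adjusted p = 0.0174; adjusted p = 0.713 with an estimated correlation). The maturation factor gene oma-2 (-0.48), clec-88 (-0.54), the aspartyl protease gene asp-2 (-0.33) and the intestinal phosphatase gene pho-1 (-0.45) were among the members that fell.

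Camera did not call the other lists at 16 h. Among cytosolic chaperones 9 fell and 3 rose (camera adjusted p = 0.217), and 4 of 8 CCT subunits fell (adjusted p = 0.111). Of the meiotic genes 11 rose and 5 fell (adjusted p = 0.129). Of the germline stem cell and meiotic entry genes 5 rose and 3 fell (5 and 4 adjusted over the list alone, adjusted p = 0.864). Of the P granule genes 7 rose and 3 fell (9 and 3 adjusted over the list alone, adjusted p = 0.111). Xenobiotic genes went both ways, 15 higher and 29 lower (adjusted p = 0.116). The camera adjusted p was 0.256 for small heat shock proteins, 0.111 for mitochondrial chaperones, 0.432 for sperm genes and 0.217 for nucleolar genes. It was 0.771 for histones, 0.589 for cell death genes, 0.455 for muscle and neuron markers, 0.685 for collagens and 0.111 for embryonic genes. For vitellogenins (adjusted p = 0.955) 0 of 6 members were called, with 0 at an unadjusted p under 0.05 in limma's test. For ribosomal proteins (adjusted p = 0.217) it was 0 of 75, with 1 at that level. For somatic gonad markers (adjusted p = 0.912) the median, the mean and the test differed in sign.

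After 24 h on auxin, 21 of 26 oocyte and eggshell genes, 26 of 38 replication genes and 5 of 11 embryonic genes fell in HSF-1-AID animals, and 27 of 32 proteasome genes rose. Of these lists the replication genes alone were called with an estimated correlation (adjusted p = 0.0198; 0.269 for oocyte, 0.175 for embryonic and 0.175 for proteasome genes). The egg-2 transcript fell from 470 ± 6.82 to 135 ± 2.28 CPM (SD, n = 3; log2 fold change -1.80, adjusted p = 3.89e-09), against 490 ± 7.06 and 468 ± 25.2 CPM in the TIR1-only strain. Its paralog egg-1 fell by 1.92 in log2. The rnr-2 transcript fell from 947 ± 29.8 to 453 ± 17.9 CPM (-1.06, adjusted p = 4.95e-07), and the replicative helicase gene mcm-5 by 0.89. The embryonic transcription factor genes elt-1 and tbx-9 fell by 2.44 and 1.86. Among proteasome genes rpn-7 was at 426 ± 40.3 and 775 ± 40 CPM (0.87, adjusted p = 7.91e-06) and pas-3 rose by 0.77. The hsp-90 transcript fell from 5171 ± 319 to 2290 ± 177 CPM (-1.18, adjusted p = 1.63e-05), hsp-1 by 0.88 (adjusted p = 0.0094), and sti-1 by 0.87. Whether effects at 24 h exceeded those at 16 h was not tested, because each time was normalized separately.

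Among genes chosen in the same way at 24 h, above the median level and not called in the same direction in the TIR1-only strain, the largest rise was that of K09H9.7 (log2 fold change 2.26, from 16.3 ± 0.995 to 78.8 ± 10.8 CPM, SD, n = 3, adjusted p = 7.56e-09). Next were C16C8.5 (1.76), R03D7.2 (1.61) and mel-46 (1.60). The largest fall among them was that of WBGene00009651 (-3.13, from 50.7 ± 1.33 to 5.71 ± 0.783 CPM, adjusted p = 2.91e-09). It was followed by R05G9.3 (-3.12), the trypsin-like protease gene try-1 (-3.02) and C50E3.13 (-2.97). In total 3999 of 10411 tested genes passed (38.4%), 1892 higher and 2107 lower. Of these, 2218 calls were beyond 1.5-fold, 881 higher and 1337 lower. The replicate numbers paired the libraries at 24 h, and with the replicate block the count was 5619.

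At 24 h camera called 10 of 27 lists, and the call of replication and mitotic genes was the only one of them that held with an estimated correlation. Of those 38 genes 26 fell and 2 rose, 31 and 2 when adjusted over the list alone, with a median of -0.65 (camera adjusted p = 8.67e-09; adjusted p = 0.0198 with an estimated correlation). Of 26 oocyte and eggshell genes 21 fell, with a median of -0.92 (adjusted p = 3.22e-10; adjusted p = 0.269 with an estimated correlation). Lectins and lysozymes (22 of 67 fell and 3 rose, median -0.22, adjusted p = 0.0282; adjusted p = 0.341 with an estimated correlation) were lower, with clec-87 at -1.88 and clec-91 at -1.73. Intestine markers (7 of 13 fell, 8 with 1 rise when adjusted over the list alone, -0.54, adjusted p = 0.0254; adjusted p = 0.708 with an estimated correlation) were lower, with pho-1 at -1.03. Embryonic genes were lower too (5 of 11 fell, -0.48, adjusted p = 0.0248; adjusted p = 0.175 with an estimated correlation). Of 32 proteasome genes 27 rose, 30 when adjusted over the list alone, with a median of 0.53 (adjusted p = 2.28e-11; adjusted p = 0.175 with an estimated correlation). Aminoacyl-tRNA synthetases (12 of 20 rose, 0.30, adjusted p = 7.09e-04; adjusted p = 0.175 with an estimated correlation) were higher, with lars-1 at 1.02. So were ER chaperones (8 of 19 rose and 1 fell, 10 and 2 when adjusted over the list alone, 0.26, adjusted p = 0.0254; adjusted p = 0.446 with an estimated correlation), with cnx-1 at 0.61 and pdi-6 at -0.64. Collagens (16 of 55 rose and 1 fell, 15 and 1 when adjusted over the list alone, 0.30, adjusted p = 0.00522; adjusted p = 0.815 with an estimated correlation) were higher, although dpy-10 fell by 2.18. Neuron markers (6 of 16 rose, 0.41, adjusted p = 0.0255; adjusted p = 0.416 with an estimated correlation) were higher, with the neuropeptide gene flp-1 at 0.0992 and 1.47 CPM.

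Among lists without a call at 24 h, 4 cytosolic chaperones rose and 4 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.785). For the CCT subunits 3 of 8 fell (1 adjusted over the list alone, adjusted p = 0.425). Of the meiotic genes 9 rose and 5 fell (11 and 5 adjusted over the list alone, adjusted p = 0.196). Of the stem cell and meiotic entry genes 2 rose and 6 fell (2 and 7 adjusted over the list alone, adjusted p = 0.224). The camera adjusted p was 0.64 for small heat shock proteins, 0.0835 for mitochondrial chaperones and 0.173 for oxidative phosphorylation. It was 0.461 for ribosomal proteins, 0.553 for nucleolar genes, 0.95 for xenobiotic genes, 0.751 for histones and 0.48 for cell death genes. For vitellogenins (median -0.37, adjusted p = 0.505) 0 of 6 were called, with 0 at an unadjusted p under 0.05 in limma's test. For muscle markers (adjusted p = 0.41) it was 0 of 16, with 1 at that level. For 3 lists the median, the mean and the test differed in sign. They were P granule genes (7 higher and 8 lower, 8 and 8 adjusted over the list alone, adjusted p = 0.889), sperm genes (2 and 2 of 5, 3 and 2 adjusted over the list alone, adjusted p = 0.975) and somatic gonad markers (adjusted p = 0.975).

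**Figure D1:**
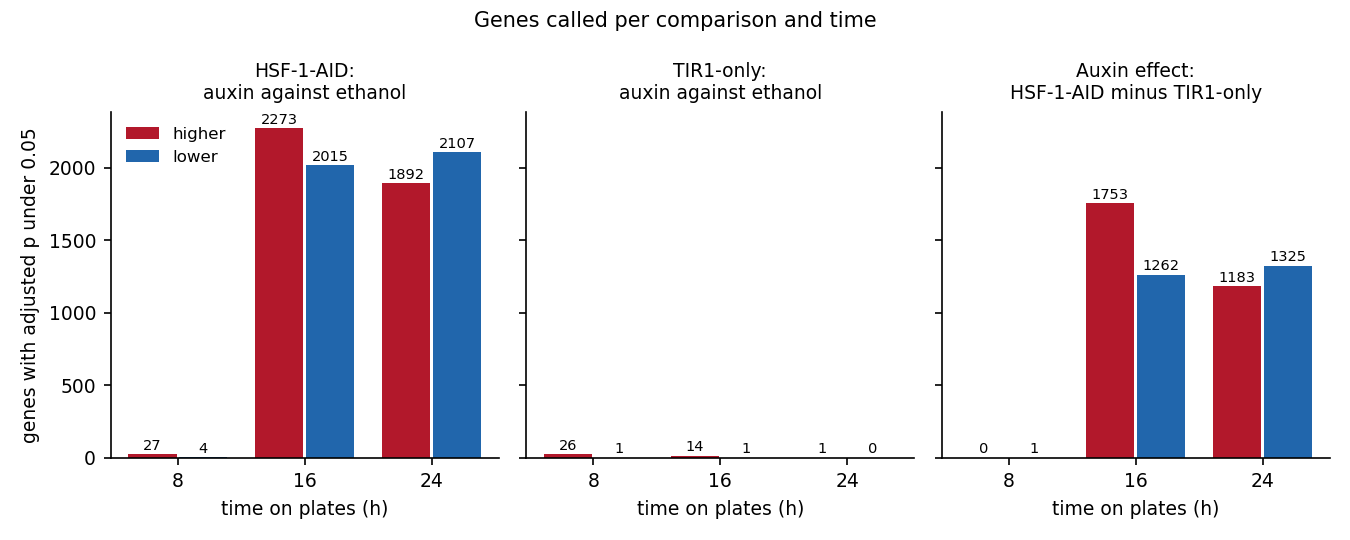
Number of genes with an adjusted p under 0.05 (y axis) by hours on plates (x axis), higher in red and lower in blue, for auxin against ethanol in each strain and for the difference between the strains' auxin effects. HSF-1-AID animals had 31 called genes at 8 h, 4288 at 16 h and 3999 at 24 h, and TIR1-only animals 27, 15 and 1.

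**Figure D2:**
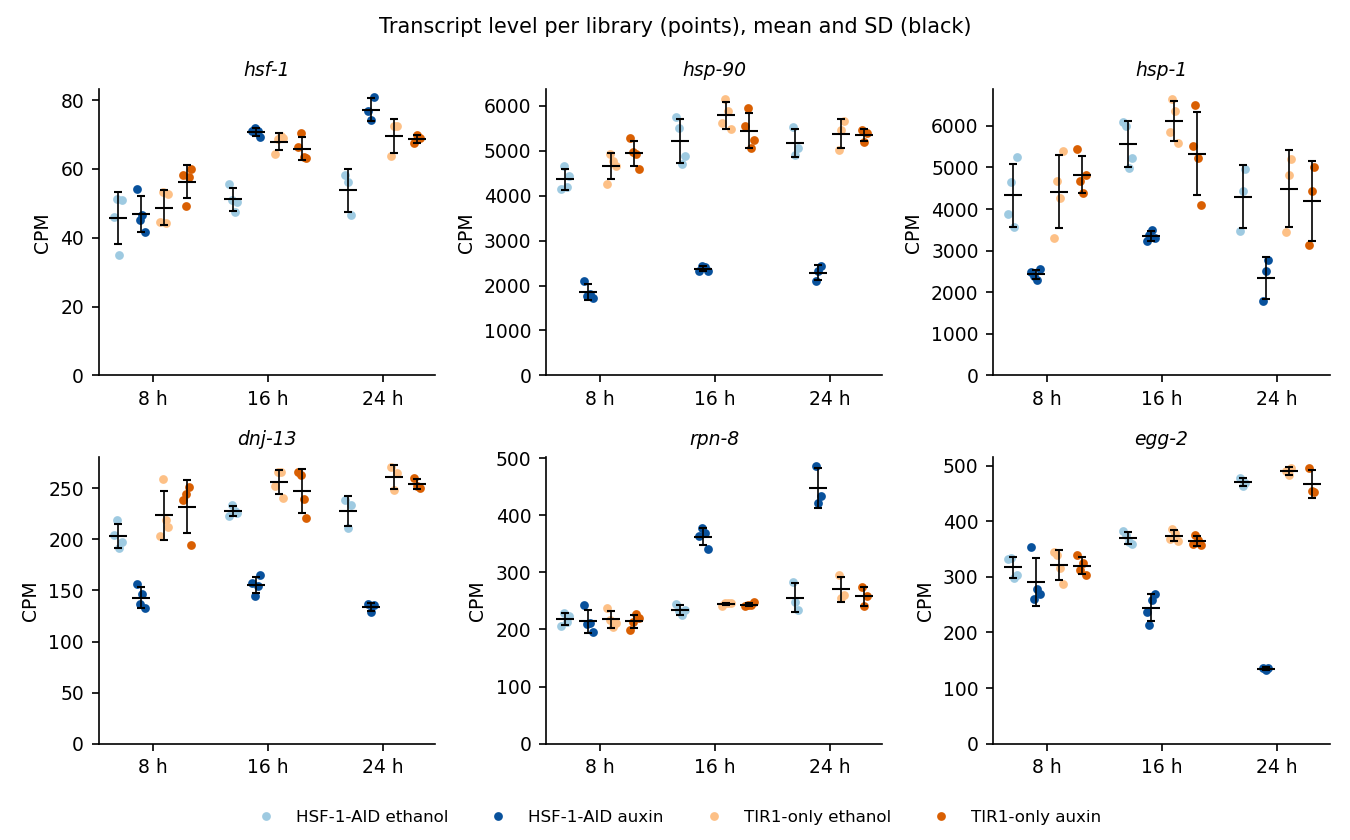
CPM (y axis, from 0) of hsf-1, hsp-90, hsp-1, dnj-13, rpn-8 and egg-2 by time and group, with each library as a point and the mean and SD in black. The hsp-90 transcript was at 1855, 2371 and 2290 CPM in HSF-1-AID animals on auxin and at 4362, 5215 and 5171 CPM on ethanol, at 8, 16 and 24 h.

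**Figure D3:**
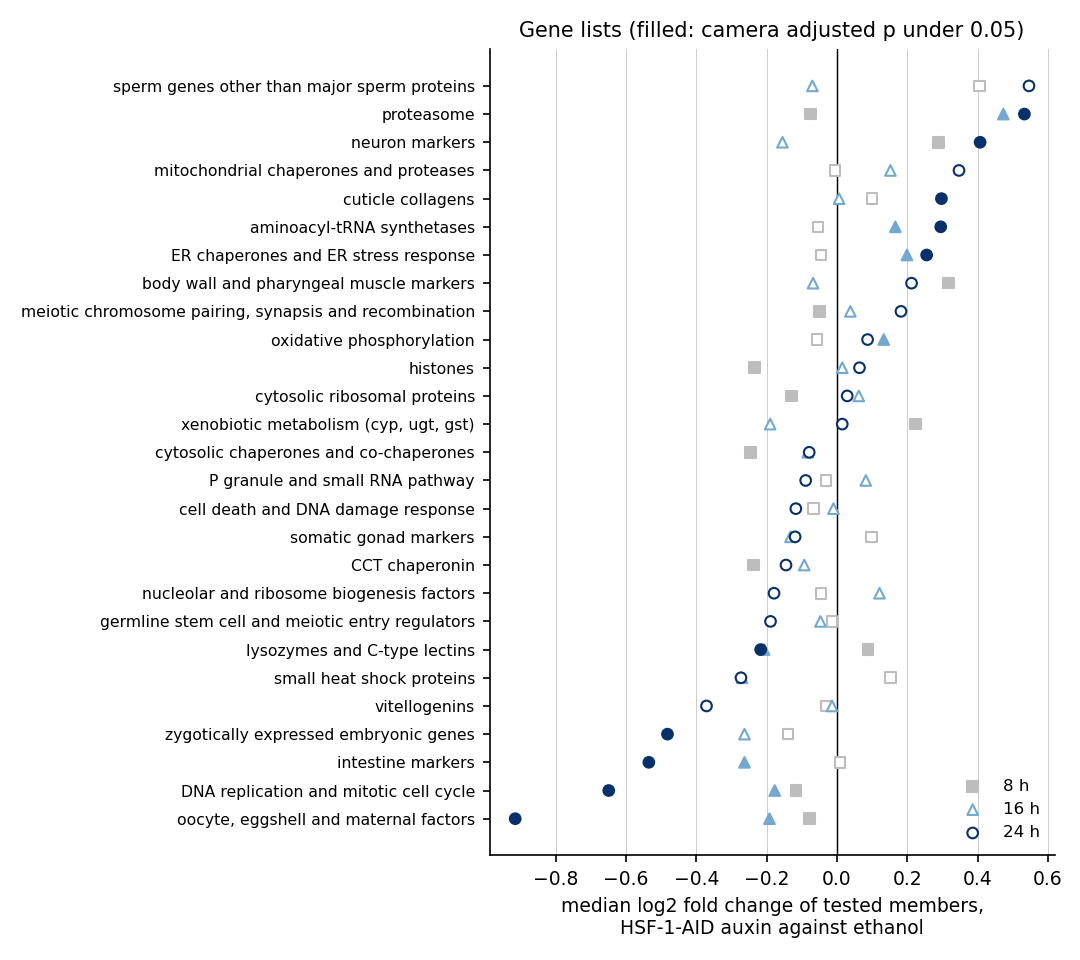
Median log2 fold change of the tested members (x axis) of the 27 gene lists tested at all 3 times (y axis), HSF-1-AID auxin against ethanol, with squares for 8 h, triangles for 16 h, circles for 24 h, and filled symbols where camera's adjusted p was under 0.05. Major sperm proteins, tested at 8 h alone, are not drawn. At 24 h oocyte and eggshell genes were lowest among called lists (-0.92) and the proteasome highest (0.53).

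Many genes were called in the same direction at 16 h and 24 h. Among genes tested at both times, 1271 rose at both, where independent lists would share 396, and 1225 fell at both, where 418 would be shared (one-sided exact hypergeometric test, p = 1e-300, the smallest value written). A further 10 and 8 calls were in opposite directions. The log2 fold changes correlated across genes, which are not independent replicates, at r = 0.732. All 4 genes that fell at 8 h also fell at 16 h (0.796 for independent lists, exact p = 0.00156), and 3 of them at 24 h (0.83, exact p = 0.0302). Of those that rose at 8 h, 11 rose at 16 h (4.29 for independent lists, exact p = 9.25e-04) and 7 at 24 h (3.48, exact p = 0.0455). Among those 11 were cyp-35A4, cyp-35C1, ugt-22, gst-5, T16G1.6 and clec-209 (under 2 identifiers with the same values). All of these were also called higher with auxin in the TIR1-only strain at 8 h and 16 h. Of the 4 that fell at 8 h, cpr-4 was also called lower there in that strain. The overlap with 8 h is therefore not particular to HSF-1 depletion. Across genes r was 0 between 8 h and 16 h and 0.222 between 8 h and 24 h.

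Auxin in the TIR1-only strain raised few genes, of which 11 of 26 at 8 h were cyp, ugt or gst genes. At 8 h the cytochrome P450 gene cyp-35A2 rose from 33.6 ± 24.3 to 170 ± 28.6 CPM (SD, n = 4; log2 fold change 2.77, adjusted p = 0.0341). In log2 cyp-35C1 rose by 2.46 (adjusted p = 0.00695) and ugt-22 by 1.59 (adjusted p = 0.00695). C29F7.2 rose by 1.81, and the cathepsin-like protease gene cpr-4 fell from 231 ± 40.9 to 122 ± 33.8 CPM (-0.94, adjusted p = 0.044). At 16 h cyp-35A2 rose from 22.2 ± 5.23 to 79.4 ± 12 CPM (1.86, adjusted p = 2.68e-05), cyp-35C1 by 1.73 and ugt-22 by 1.10, while F44E7.5 fell by 0.28 (adjusted p = 0.0256). In total 27 genes passed at 8 h (26 higher), 15 at 16 h (14 higher) and 1 at 24 h. At 24 h it was K12D9.1 (chromosome V, 3014485 to 3016049), named after its values were seen. It had 0 reads in every ethanol library and 1.251 ± 0.133 CPM on auxin (SD, n = 3; at least 19.8-fold higher, against a floor of 3 reads over the group; adjusted p = 5.13e-04). It rose in HSF-1-AID animals too (adjusted p = 9.5e-06). With the replicate block 32 genes passed at 24 h, 29 higher, cyp-35A4 among them (0.909 and 8.56 CPM; adjusted p = 0.215 without the block and 0.00351 with it). The members of the cyp-35A family are close copies, so their separate values depend on how shared reads were assigned.

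Several of these calls were lost when single libraries were left out. The TIR1-only count at 8 h was 11 without ethanol replicate 3, 13 without ethanol replicate 4, 8 without auxin replicate 1, 15 without auxin replicate 3 and 11 without auxin replicate 4. It was 0 without the 4 deeper libraries or with only the 2 groups compared. At 16 h it was 9 without ethanol replicate 2 and 9 without auxin replicate 1. The 8 h call of cpr-4 was lost without any TIR1-only library except ethanol replicate 3 and auxin replicate 2 (adjusted p from 0.00792 to 0.229, log2 fold change from -1.10 to -0.80). The 16 h call of F44E7.5 was lost without any except ethanol replicate 4 and auxin replicate 2 (adjusted p from 0.0461 to 0.118, log2 fold change from -0.29 to -0.26). That of cyp-35A2 at 8 h was lost without 5 of the 8 libraries, those other than ethanol replicates 1 and 2 and auxin replicate 2 (adjusted p from 0.0142 to 0.141, log2 fold change from 2.12 to 3.16).

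As a list, xenobiotic genes rose in the TIR1-only strain at 8 h (11 called, 16 when adjusted over the list alone, median 0.03, camera adjusted p = 6.19e-06; adjusted p = 0.868 with an estimated correlation). They also rose at 16 h (8 called, 16 when adjusted over the list alone, 0.12, adjusted p = 4.59e-14; adjusted p = 0.182 with an estimated correlation). At 24 h 0 of 110 passed in limma's test, with 19 at an unadjusted p under 0.05 and 9 when adjusted over the list alone (0.13, adjusted p = 1.83e-08; adjusted p = 0.595 with an estimated correlation). Collagens were lower at 8 h (-0.27, adjusted p = 9.16e-10, or 0.868 with an estimated correlation) and oocyte genes higher (0.21, adjusted p = 3.51e-08, or 0.868 with an estimated correlation). Neither of these lists held a gene that limma called there. Camera called 9, 8 and 4 lists at 8, 16 and 24 h (2 at 24 h with identical values counted once), and 0 of them with an estimated correlation. The genes called in both strains in the same direction numbered 18 higher and 1 lower at 8 h, 14 higher and 1 lower at 16 h and 1 at 24 h. For independent lists the shared rises would be 0.064, 3.13 and 0.182.

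The auxin effect on hsp-90 differed between the strains at every time (difference in log2 -1.32, adjusted p = 0.00673 at 8 h; -1.04, adjusted p = 1.61e-05 at 16 h; -1.17, adjusted p = 6.47e-04 at 24 h). At 8 h hsp-90 was the 1 gene of 10971 that passed, with 378 at an unadjusted p under 0.05, and it missed the threshold when the deeper libraries were left out (-1.31, adjusted p = 0.123). For hsp-1 the difference did not pass at 8 h (-0.97, adjusted p = 0.973). At 24 h its adjusted p was 0.111 without the replicate block and 4.81e-05 with it (-0.77), and 0.0477 without TIR1-only auxin replicate 1. At 16 h hsp-1 passed (-0.52, adjusted p = 0.033), and the call was lost without any 1 of 9 of the 16 libraries (adjusted p up to 0.0613). These were HSF-1-AID ethanol replicates 1 and 2, HSF-1-AID auxin replicates 1, 2 and 4, TIR1-only ethanol replicates 1 and 4 and TIR1-only auxin replicates 1 and 3. At 16 h 3015 genes passed, 1753 higher and 1262 lower, with mel-46 at 1.35, eel-1 at 1.29, WBGene00009651 at -1.51 and Y4C6A.3 at -1.42. At 24 h 2508 passed, 1183 higher and 1325 lower, and 4332 (2118 higher, 2214 lower) with the replicate block. There K09H9.7 was at 2.34, R03D7.2 at 1.90 (adjusted p = 0.0206), WBGene00009651 at -3.22 and try-1 at -3.11. The R03D7.2 call was lost without HSF-1-AID auxin replicate 3 (1.68) or TIR1-only ethanol replicate 3 (1.70).

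All 32 proteasome genes had a larger auxin response in HSF-1-AID than in TIR1-only animals at 16 h (median difference 0.53, camera adjusted p = 4.5e-24; adjusted p = 0.404 with an estimated correlation), with rpn-8 at 0.64. At 24 h 23 passed, 26 when adjusted over the list alone (0.54, adjusted p = 5.85e-11; adjusted p = 0.139 with an estimated correlation), with rpn-7 at 0.88. At 24 h 21 replication genes were lower (21 with 1 higher when adjusted over the list alone, -0.59, adjusted p = 1.5e-07; adjusted p = 0.0328 with an estimated correlation), with rnr-2 at -0.99. So were 18 oocyte genes (-0.86, adjusted p = 4.99e-10; adjusted p = 0.222 with an estimated correlation), with egg-2 at -1.73. Aminoacyl-tRNA synthetases were higher at 16 h (11 of 20, 12 adjusted over the list alone, 0.15, adjusted p = 0.0011; adjusted p = 0.421 with an estimated correlation). They were higher at 24 h as well (10 of 20, 11 adjusted over the list alone, 0.37, adjusted p = 2.91e-04; adjusted p = 0.139 with an estimated correlation). Xenobiotic genes were lower at 16 h (23 lower and 3 higher, 22 and 3 adjusted over the list alone, -0.34, adjusted p = 5.41e-05; adjusted p = 0.421 with an estimated correlation). At 8 h cytosolic chaperones were lower (1 called, 6 when adjusted over the list alone, -0.21, adjusted p = 8.37e-08; adjusted p = 0.0923 with an estimated correlation). Camera called 16, 9 and 11 lists at 8, 16 and 24 h, and 0, 0 and 1 with an estimated correlation.

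**Figure D4:**
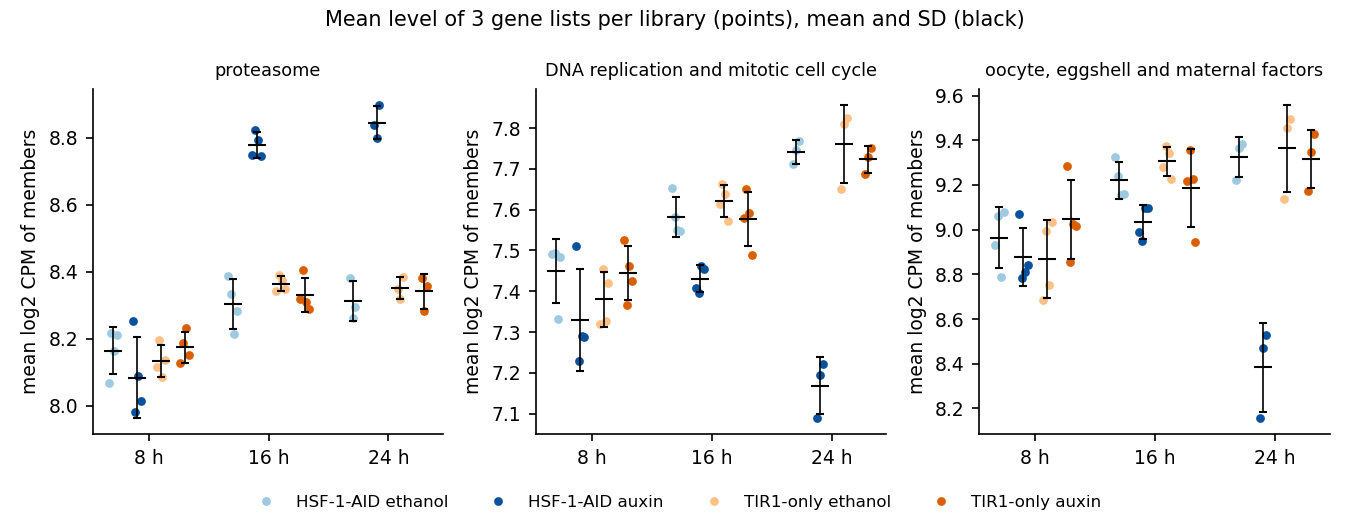
Mean log2 CPM of the members (y axis, not from 0) of the proteasome, replication and oocyte lists by time and group, with each library as a point and the mean and SD in black. For the proteasome the HSF-1-AID auxin libraries lay from 8.74 to 8.82 at 16 h and from 8.80 to 8.90 at 24 h, above the highest of the other libraries at 8.40 and 8.38.

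On ethanol the strains differed in few genes. The gene cTel55X.1, near the right end of the X chromosome (17714961 to 17718726), was lower in HSF-1-AID than in TIR1-only animals at every time. The levels of cTel55X.1 were 0.204 ± 0.409 against 7.15 ± 2.16 CPM at 8 h (SD, n = 4; adjusted p = 0.0156) and 0.181 ± 0.362 against 8.41 ± 0.607 CPM at 16 h (SD, n = 4; adjusted p = 0.0326). At 24 h it had 0 reads in every HSF-1-AID ethanol library and 6.91 ± 1.21 CPM in the TIR1-only strain (SD, n = 3; at least 117.4-fold lower, against a floor of 3 reads over the group; adjusted p = 1.07e-08). The hsf-1 transcript was lower in HSF-1-AID animals at 16 h (log2 difference -0.41, adjusted p = 0.00203; adjusted p = 0.0571 with only the 2 groups compared), and at 24 h the difference was -0.38 (adjusted p = 1). At 16 h Y34F4.3 (chromosome III, 1012166 to 1016180) was at 0.579 against 1.74 CPM (-1.49, adjusted p = 0.0326). cTel55X.1 and Y34F4.3 were named after their values were seen. These were all the calls, 1 at 8 h, 3 at 16 h and 1 at 24 h, or 7 (3 higher, 4 lower) at 24 h with the replicate block.

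The 16 h call of hsf-1 held without any 1 of the 8 ethanol libraries (adjusted p from 4.14e-04 to 0.0171). That of cTel55X.1 was lost at 8 h and 16 h without any ethanol library except HSF-1-AID replicate 4, with adjusted p from 2.14e-04 to 0.112 at 8 h and from 0.00357 to 0.177 at 16 h. Its log2 difference ranged from -6.47 to -5.30 at 8 h and from -7.49 to -6.14 at 16 h. The call of Y34F4.3 was lost without any of the 8 ethanol libraries (adjusted p from 0.0518 to 0.185, log2 difference from -1.61 to -1.37). The 8 h count was therefore 0 without any ethanol library except HSF-1-AID replicate 4, and the 16 h count was 1 without HSF-1-AID replicate 2 or 3 or any TIR1-only replicate. Among lists, cytosolic chaperones were lower on ethanol in HSF-1-AID animals at 16 h (median -0.12, camera adjusted p = 2.08e-09; adjusted p = 0.0319 with an estimated correlation). There 0 of 25 were called by limma, with 10 at an unadjusted p under 0.05, and 8 fell and 1 rose when adjusted over the list alone. The CCT subunits were lower too (-0.20, adjusted p = 1.05e-16; adjusted p = 0.0319 with an estimated correlation), with cct-3 at -0.18 and cct-5 at -0.23. There 0 of 8 were called by limma, with 7 at an unadjusted p under 0.05 and 7 lower when adjusted over the list alone. At 8 h small heat shock proteins were lower (-0.38, adjusted p = 5.51e-11; adjusted p = 0.0217 with an estimated correlation), but hsp-16.1 and hsp-16.48 each entered under 2 identifiers with identical values. Counted once, they left a median of -0.19 (adjusted p = 1.22e-04; adjusted p = 0.173 with an estimated correlation). Of these 8 members 0 were called by limma, with 2 at an unadjusted p under 0.05 and 2 lower when adjusted over the list alone. Camera called 8, 15 and 5 lists at 8, 16 and 24 h, and 1, 2 and 0 with an estimated correlation. With identical values counted once these were 8, 14 and 5, and 0, 2 and 0. Of the 15 lists called at 16 h with the preset correlation, 14 were lower in HSF-1-AID animals and 1 was higher. By that test a fall was not particular to chaperones. The 2 lists called with an estimated correlation were the cytosolic chaperones and the CCT subunits.

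The authors' table of fold changes came closest to HSF-1-AID animals on auxin against the mean of the other 3 groups, with r across genes of 0.966 at 8 h, 0.995 at 16 h and 0.985 at 24 h. Against HSF-1-AID ethanol alone r was 0.869, 0.955 and 0.967. For hsp-90 at 8 h the table gave a log2 fold change of -1.33 with an FDR of 1.22e-36, and for sti-1 -0.57 with an FDR of 7.7e-05. In limma's test against ethanol sti-1 was at -0.43 (adjusted p = 0.169). At an FDR under 0.05 the table held 12 genes at 8 h, all of them lower, 5088 at 16 h (2567 higher) and 5167 at 24 h (2480 higher). It shared 3, 4071 and 3892 genes in the same direction with the calls of limma at 8, 16 and 24 h.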

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

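Chosen only after the result was seen were the tests of the pals genes, of the authors' scaling for the proteasome, of germline RNA and of embryos; the splits of the libraries and the proteasome's drift between libraries were set before.

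Groups of 4 libraries were checked for several quantities, such as depth, rRNA share and levels of named genes, in 137 combinations of group and quantity. In 12 of them 1 library lay far from the others by Dixon's ratio. Chance alone would give about 1 in 20 combinations, or 6.85. At 8 h the libraries numbered 4 held more reads, 48.03 M reads in HSF-1-AID ethanol (others 14.3 to 18.3), 50.66 M reads in HSF-1-AID auxin (others 17.2 to 19.4) and 44.84 M reads in TIR1-only ethanol (others 14.5 to 18.8). The transcript cTel55X.1 was at 0.8172 CPM in HSF-1-AID ethanol 8 h replicate 4 and at 0.7241 CPM in HSF-1-AID ethanol 16 h replicate 4, with 0 in the other replicates. The auxin groups had the same pattern, with 0.765 CPM at 8 h and 1.40 CPM at 16 h in HSF-1-AID replicate 4 and 0 in the others. Reads of rRNA were 3.232% in TIR1-only ethanol 16 h replicate 4 (others 2.02% to 2.11%). In HSF-1-AID auxin 16 h replicate 2, mel-46 was at 160.8 CPM (others 134.7 to 136.8) and tra-1 at 49.48 CPM (others 39.8 to 41.2). In ethanol libraries at 16 h, pho-1 was at 63.97 CPM in HSF-1-AID replicate 1 (others 68.7 to 69.7) and hsf-1 at 64.26 CPM in TIR1-only replicate 1 (others 68.7 to 69.5). The co-chaperone gene ahsa-1 was at 268.9 CPM in HSF-1-AID ethanol 16 h replicate 3 (others 287.8 to 291.7) and at 335.3 CPM in TIR1-only ethanol 16 h replicate 2 (others 320.8 to 322.9).

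The auxin effect differed between the strains, by the test of the difference itself, in 1 gene at 8 h, 3015 at 16 h and 2508 at 24 h. Other splits of the same libraries were fitted in the same way. At 8 h 5 of 100 splits gave at least 1 gene, with a highest other count of 1. At 16 h 1 of 100 splits, the real one, gave 3015, with a highest other count of 2470. At 24 h 6 of 100 splits gave at least 2508, with a highest other count of 3461. Of the other splits, 3 at 8 h, 3 at 16 h and 9 at 24 h kept the HSF-1-AID libraries apart by treatment and so still contain the depletion effect. They gave at most 1, 2470 and 3461 genes, and all the rest at most 1, 0 and 0. At each time the splits that keep the depletion effect are too few for a share under 0.05. Among the 14 splits at 24 h that parted every same-number pair, the highest other count was 2502.

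For auxin against ethanol in HSF-1-AID animals, 1 of 35 splits gave as many as the real 31 genes at 8 h. At 16 h 1 of 35 gave as many as 4288, and the highest other count was 0 at both times. These shares are under 0.05, but they are the smallest that 35 splits can give and were not adjusted over the comparisons. Splits that mix auxin and ethanol libraries also add any real effect to the spread between libraries, which lowers their counts. In TIR1-only animals 1 of 35 splits gave as many as 27 genes at 8 h (highest other 1) and 1 of 35 as many as 15 at 16 h (highest other 0). The same limits hold there. At 24 h 3 against 3 libraries make 10 splits, too few for a share under 0.05. There the real split gave 3999 genes in HSF-1-AID animals and 1 in TIR1-only animals, 1 of 10 splits reached each count, and the highest other was 0 for both. The numbers pair the libraries at 24 h, and the highest other count among the 4 splits that parted all 3 pairs was 0 for both as well. For the strains on ethanol, 3 of 35 splits reached the real 1 gene at 8 h, with a highest other count of 76. At 16 h 2 of 35 reached the real 3, with a highest other of 7, so chance was not excluded for either count. Among the 8 splits that parted every same-number pair the highest other was 0 at both times, but 8 are too few for a share under 0.05. The gene called at 8 h, cTel55X.1, did separate the strains in every library of all 3 times (at most 1.40 CPM in HSF-1-AID, at least 4.96 CPM in TIR1-only animals). The split with 76 genes set replicates 1 and 3 of both strains against 2 and 4, and that with 7 set replicates 1 and 4 against 2 and 3. The first points to a structure of the samples beside strain. At 24 h 2 of 10 splits reached the real 1 gene, with a highest other of 1 from a split parting fewer pairs, and 10 splits are too few for a share under 0.05.

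At 24 h 8 of 16 tested pals genes, a family known from responses to intracellular infection, rose in HSF-1-AID animals on auxin. They were pals-26, pals-27, pals-29, pals-30, pals-33, pals-37, pals-38 and pals-39, named after their values were seen; pals-22 fell by 0.62. pals-26 was at 53.1 ± 14.7 CPM (SD, n = 3) against 0.317 CPM on ethanol, and pals-29 at least 61.7-fold above the floor of 3 reads over an ethanol group with 0 reads. In the other 9 libraries all 8 were at 0.899 CPM or less. They thus passed the filter of 1 CPM mainly through the 3 auxin libraries. That all 8 lay above the other 9 libraries in each auxin library was therefore largely set in advance and does not test for 1 odd library. Their lowest auxin library was still at 2.83 (pals-29) to 39.1 CPM (pals-26). The authors' scaling moves all genes of a library alike and holds their median near 0 (-0.012 in log2 for all other genes). Only a rise relative to other genes is therefore shown. The family's camera adjusted p over 13 gene sets was 0.00016 (0.178 with an estimated correlation). Like the count of 8 of 16, it rests on members that the filter let in because they rose, and at 16 h only 8 pals genes were tested. At 16 h pals-26 was at 1.09 to 5.86 CPM on auxin and at most 0.556 CPM elsewhere. An infection of these animals or reads shared among copies may contribute and were not tested.

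Proteasome genes rose as a set at 16 h and 24 h by camera's preset correlation, a call lost with an estimated one (adjusted p = 0.464 and 0.175 with an estimated correlation). Against a drift of the whole list between libraries, the lowest HSF-1-AID auxin library lay 0.357 (16 h) and 0.419 (24 h) in log2 above the highest HSF-1-AID ethanol library, while the widest range within any group was 0.173 and 0.117. The list's median exceeded that of all other genes by 0.506 and 0.547. The authors' scaling holds the median of all tested genes close to no change (-0.0318 and -0.0114 in log2). This comparison therefore shows only a rise relative to other genes and does not test the scaling. A response of the animals to HSF-1 depletion may underlie the rise, as a hypothesis found on the same data that these tests do not decide.

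Oocyte and replication genes fell at 24 h, with medians of -0.915 and -0.649 (adjusted p = 0.269 and 0.0198 with an estimated correlation). A smaller share of germline RNA alone would lower germline lists alike. The median of meiotic genes was 0.182 (quartiles -0.033 and 0.272), above both, so these lists did not fall alike. More stem cell and meiotic entry genes were called lower than higher, and P granule genes went both ways. All values are relative to other genes, so the lists do not decide whether the share of germline RNA changed. A change in which germ cells are present stays open and was not tested. Fewer embryos in the worms may contribute: 5 of 11 embryonic genes fell, which does not decide it, since genes may also be expressed in the germline.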

How the results depend on the processing

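Chosen only after seeing the data were the tests with quality weights, voom, a pseudocount of 0.5, the contrast with the mean of 3 groups, identical values counted once, and the deeper or highest-rRNA libraries left out; the cause of each change below was not tested unless named. What depth limits was not separated from the number and spread of replicates: in simulated data 44%, 84% and 52% of 1.5-fold changes were recovered at 8, 16 and 24 h. Fits with edgeR and DESeq2 were not run, although whole reads could be recovered from the log2 values. Of fits on reads, only limma voom was run. Removing the filter, pseudocounts of 0.1 and 0.5, median-of-ratios size factors and voom left every count of genes within 1.5 times its value, with voom calling 34, 4314 and 4032 depletion genes.

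Library quality weights gave 285 depletion genes at 8 h (31), 3 for the strain difference in the auxin effect at 8 h (1), and 0, 13 and 2 for the strains on ethanol at 8, 16 and 24 h (1, 3 and 1). Leaving out the 4 deeper libraries gave 3 depletion genes, 0 in TIR1-only animals (27) and 0 for the difference in the auxin effect at 8 h; fewer libraries were tested. Leaving out the highest-rRNA library gave 11 in TIR1-only animals and 0 for the strains on ethanol at 8 h. A pseudocount of 2 gave 16 in TIR1-only animals at 8 h. With only the 2 groups compared, fewer degrees of freedom gave 0 in TIR1-only animals at 8 h and 0 and 0 for the strains on ethanol at 8 and 16 h. A minimum of 1.5-fold left 725 (4288) and 2218 (3999) depletion genes at 16 and 24 h and 834 (3015) for the difference in the auxin effect at 16 h, since many changes were smaller.

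The replicate block at 24 h gave 32 genes in TIR1-only animals (1), 4332 for the difference in the auxin effect (2508) and 7 for the strains on ethanol (1). At 8 h it gave 42, 27, 1 and 1 genes and at 16 h 4573, 14, 3425 and 3, for depletion, TIR1-only, the difference and the strains on ethanol. With an estimated correlation 1, 0 and 1 lists were called for depletion at 8, 16 and 24 h (13, 8 and 10), and 13, 8 and 10 with identical values counted once. At an adjusted p under 0.01 the calls shared between 8 and 16 h were 3 higher and 1 lower (exact p = 0.0624 and 0.12, against 9.25e-04 and 0.00156), between 8 and 24 h 2 and 1 (exact p = 0.134 and 0.145, against 0.0455 and 0.0302), and between 16 and 24 h 832 and 765, since fewer genes passed.

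Leaving out each library in turn gave 9 to 32 depletion genes at 8 h, 3481 to 4283 at 16 h and 3316 to 3552 at 24 h. In TIR1-only animals it gave 8 to 28, 9 to 21 and 1, for the difference in the auxin effect 1, 2488 to 3482 and 2066 to 2518, and for the strains on ethanol 0 to 1, 1 to 2 and 1. Of 2413 alternative values of results for named genes, 137 lost the call, 9 gained it and 0 reversed direction with a call on either side. The other 2267 kept the call or its absence. They include uncalled values that changed sign, such as hsf-1 in depletion at 8 h (log2 fold change from -0.08 to 0.10 with single libraries left out). Of the called results 70 kept the call under every alternative run, hsp-90 in depletion among them at all 3 times. The 8 h calls of hsp-1 (pseudocount 2, adjusted p = 0.0624) and dnj-13 (highest-rRNA library left out, adjusted p = 0.0532) were among those lost.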

Other observations

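The tests here were chosen only after the data were seen, except the correlation of chaperone genes between times.

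Gene families outside the fixed lists were tested with camera, adjusted over 13 sets. Mitochondrially encoded genes fell with depletion at 16 h (12 of 13, median -0.89, adjusted p = 3.83e-05; adjusted p = 0.509 with an estimated correlation). The set was not called at 8 h (median 0.31, adjusted p = 0.0528) or 24 h (3 of 14 fell, -0.50, adjusted p = 0.115). On ethanol at 16 h it was higher in HSF-1-AID than in TIR1-only animals (0.41, adjusted p = 1.42e-11, or 0.247 with an estimated correlation). The same difference was negative at 8 h (-0.23, adjusted p = 0.017, or 0.947 with an estimated correlation). It was positive at 24 h (0.51, adjusted p = 1.65e-07, or 0.764 with an estimated correlation). The libraries were poly(A)-enriched, which bears on the level of mitochondrial transcripts. Genes of the X chromosome were lower at 16 h (median -0.14, adjusted p = 6.89e-04; adjusted p = 0.509 with an estimated correlation) and 24 h (404 lower and 89 higher of 1407, -0.21, adjusted p = 2.98e-04; adjusted p = 0.239 with an estimated correlation), but higher at 8 h (2 higher and 0 lower of 1506 by limma, median 0.07, adjusted p = 1.21e-04; adjusted p = 0.409 with an estimated correlation). Nuclear hormone receptor nhr genes were lower at 24 h (36 lower and 7 higher of 129, -0.20, adjusted p = 0.0207; adjusted p = 0.0366 with an estimated correlation). F-box genes were lower at 16 h (29 lower and 12 higher of 80, -0.43, adjusted p = 0.00237, or 0.509 with an estimated correlation). Between the strains on ethanol at 16 h they were higher in HSF-1-AID animals (0.12, adjusted p = 8.85e-09, or 0.191 with an estimated correlation). At 8 h 1 of 6 tested irg genes rose with auxin in HSF-1-AID animals (median 0.79, adjusted p = 6.96e-06; adjusted p = 0.0227 with an estimated correlation) and 2 of 6 in TIR1-only animals (0.72, adjusted p = 5.73e-05; adjusted p = 0.0419 with an estimated correlation).

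The transcript cTel55X.1 separated the strains in every library. It had 0 reads in 6 of 8, 6 of 8 and 6 of 6 HSF-1-AID libraries at 8, 16 and 24 h, with highest values of 0.817 and 1.40 CPM at 8 h and 16 h, and lay from 4.96 to 9.55, 6.67 to 8.99 and 5.64 to 8.19 CPM in TIR1-only libraries.

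Lower chaperone transcripts in the HSF-1-AID strain on ethanol at 16 h might come from loss of HSF-1 without auxin. The ethanol difference would then follow the depletion effect gene by gene, which was tested between times with no libraries in common, over 33 chaperone and CCT genes. Between ethanol at 16 h and depletion at 8 h r was -0.049 (rho 0.234, one-sided permutation p = 0.6, adjusted p = 0.6; r -0.09 without the 2 genes farthest from the median), so this prediction was not met. In the other two pairs of times r was 0.431 (ethanol 8 h, depletion 16 h; rho 0.577, p = 0.011, adjusted p = 0.016; 0.376 without 2 genes) and 0.422 (ethanol 24 h, depletion 8 h; rho 0.433, p = 0.008, adjusted p = 0.016; 0.421 without 2 genes). These are correlations across genes, which are not independent replicates, and adjusted over 3 pairs of times; the p-values are for r.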
